A study of Homo sapiens with 6 samples.

How the data were processed

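Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on 2 human lung epithelial cell lines without treatment. BRD8 was mapped in Calu3, a lung adenocarcinoma line, and in 16HBE14o-, a bronchial epithelial line. CTCF was mapped in Calu3. The 6 samples were 2 replicates of each of these 3 experiments. Per the labels, BRD8 was precipitated from Calu3 with an Active Motif antibody and CTCF with a Millipore antibody, from sonicated nuclei.

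Per the series' design text, the authors made 1 peak list for each experiment from its 2 replicates by the irreproducible discovery rate (IDR), which keeps peaks that rank alike in both replicates. The 3 deposited lists are in narrowPeak format on hg19, per the file headers. The aligner, the peak caller, the control library and the IDR settings were not given in the sources used here. Values for single replicates were not used here, so a list is 1 pooled value per experiment, no test across replicates could be made and the sequencing depth behind each list is unknown. The deposited score columns hold the authors' score, which ranges from 540 to 1000 in each list, the authors' signal, by which every list is sorted, and a further score in the column for q-values. That last column falls below 0 for 46 peaks of the 16HBE14o- list. The deposited p-value column holds -1 throughout and was not used. The last deposited column, another kind of number, gives the distance of the summit from the peak's start. The authors' signal was used to rank peaks within a list, as deciles or as a percentile where 100 is the strongest end. It is also given as such for named peaks and as a median for classes of CTCF peaks. Signals of different lists may not be on the same scale and were not compared.

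Peak sets were compared by overlap of at least 1 bp. A share of overlapping peaks is given with its 95% exact Clopper-Pearson interval, which covers counting error only. Chance overlap was described with 1000 placements of the second list at uniform positions within its chromosomes, and with 1000 placements in which each of its peaks was moved by 10 to 100 kb. Peaks called in both lines and peaks called in 1 line were compared for CTCF overlap by two-sided Fisher's exact test on peaks, with the sample odds ratio and its Woolf interval. The probability that a peak of one class outranks a peak of the other was tested with 100000 permutations, two-sided, so that 1e-05 is the smallest p these tests can give. Peaks are not replicates, and every p-value over peaks describes these lists and not the spread between cultures. Benjamini-Hochberg adjustment was applied within each family of tests. Chromosome arms with at least 20 BRD8 peaks over both lists were compared by Fisher's exact test on the numbers of peaks, and the ratio of list shares has an exact interval from the binomial split of an arm's peaks between the lists.

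Overlaps were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the counts were identical to those of bedtools 2.31.1. The overlap function was tested on simulated data made from the 9769 Calu3 BRD8 peaks: where 20.4%, 49.6% or 79.4% of the peaks were given a partner, 100% of those partners were found. Each partner was placed over the summit of its peak, so an overlap was certain and the test checks the code only. Chromosome lengths of hg19 came from GenomeInfoDb 1.38.1 and cytogenetic bands from circlize 0.4.16, after a check that both hold the same chromosome lengths. Figures were drawn with matplotlib 3.10.9.

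The following were fixed before the data were examined: the number of peaks per list, the shares of BRD8 peaks shared between the lines in both directions, the shares at CTCF peaks, the CTCF overlap and signal rank of shared peaks against peaks of 1 line, and the distance between BRD8 and CTCF summits in Calu3. Random placement at uniform positions was fixed with them. The other comparisons were chosen after the data were examined: the differences between the lines in CTCF overlap and its odds ratio, the deciles, the ranks of BRD8 peaks with against without CTCF, the shares and classes of CTCF peaks by BRD8, the merged regions, the summit distances that involve 16HBE14o-, the arms and bands, the alternatives for these and for the share of 16HBE14o- peaks met by Calu3 peaks, and the placements moved by 10 to 100 kb. The tests of explanations in the closing section were not part of the plan either; those of secondary summits, of a background shared by the Calu3 libraries and of the mean percentile of all CTCF peaks were written after related values had been seen. The other settings fixed beforehand were a reciprocal overlap of at least 50%, summits within 100 bp, the upper 50% of each list by signal, lists of equal length, peaks set to 200 bp around the summit, and autosomes only. Added later were overlapping peaks merged into regions, also with the strongest summits of merged regions within 100 bp. Regions are named by a rule fixed beforehand: the 5 peaks of highest signal in each list, the 5 of highest signal in 1 line with none within 1 kb in the other, and the 5 BRD8 peaks of highest summed rank with CTCF. The strongest BRD8 peaks of 1 line without a CTCF peak were added after the values were seen. Starts and ends are counted from 1.

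An hg19 gene annotation or genome sequence was not used here. Promoter overlap, CTCF overlap of promoter against distal BRD8 peaks, the lists of genes, the CTCF motif and base composition were planned and not run, and no gene is assigned to a region.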

Results

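The data were 3 lists of ChIP-seq peaks on hg19, each pooled by the authors from 2 replicates. BRD8 is a bromodomain subunit of the NuA4/TIP60 histone acetyltransferase complex, and CTCF is a zinc finger protein that binds insulators and loop anchors. Of the Calu3 BRD8 list, 9769 peaks covered 4.13 Mb. The 16HBE14o- BRD8 list held 9505 peaks over 2.13 Mb and the Calu3 CTCF list 16413 peaks over 4.31 Mb. Each list had peaks on 23 chromosomes, the autosomes and X. Widths were nearly uniform within a list: 476 bp for 94.2% of Calu3 BRD8 peaks, 224 bp for 99.97% of 16HBE14o- BRD8 peaks and 290 bp for 74.1% of CTCF peaks. In the Calu3 BRD8 list, neighbouring peaks overlapped, so that its peaks formed 8184 separate regions, of which 1538 (18.8%) held more than 1 peak. The 16HBE14o- BRD8 peaks formed 9504 regions and the CTCF peaks 16071. With no values per replicate, the intervals below cover counting error only.

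The first comparison asked how much of the BRD8 map is common to the 2 lung epithelial lines. About equal parts of the Calu3 BRD8 peaks were and were not called in 16HBE14o-: 4890 of 9769 overlapped a 16HBE14o- peak, or 50.1% (95% interval 49.1 to 51.1%). In the other direction 4127 of 9505 16HBE14o- peaks overlapped a Calu3 peak, or 43.4% (42.4 to 44.4%). Strong peaks were shared far more often than weak ones. Lists were divided into deciles by signal. Of the strongest decile of the Calu3 list 80.7% were shared, and of decile 8 34.9%, with 38.6% in the weakest; after overlapping peaks were merged the weakest decile stood at 22.3%, and with peaks set to 200 bp at 17.7%. In the 16HBE14o- list the share fell from 73.3% in the strongest decile to 22.5% in the weakest. Random placement gave a mean overlap of 0.260% for Calu3 peaks and at most 0.471% in 1000 draws, and moving the 16HBE14o- peaks by 10 to 100 kb gave 0.590%. A shared peak outranked a peak of that line alone with probability 0.654 in Calu3 and 0.680 in 16HBE14o- (permutation p = 1e-05 for each, the smallest possible, and 1e-05 after adjustment over 4 rank tests). Because the 2 BRD8 lists have different peak widths, the share depends on the overlap required, and a reciprocal overlap of at least 50% left 4.37% of Calu3 peaks shared.

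The strongest BRD8 sites illustrate this. The peak of highest signal in Calu3 lay in 20q13.32 (hg19 chromosome 20, 56784786 to 56785386, signal 330.2). It overlapped the peak ranked 2 in 16HBE14o- (56784977 to 56785200, signal 160.7). The Calu3 peaks ranked 2 to 5 lay in 1q42.12 (chromosome 1, 225662619 to 225663073), 17q12 (chromosome 17, 36762544 to 36763028), 3q27.1 (chromosome 3, 184278998 to 184279470) and 9p13.3 (chromosome 9, 33721986 to 33722520). In 16HBE14o- the peak of highest signal lay in 9q34.13 (chromosome 9, 134615518 to 134615615, signal 179), followed after 20q13.32 by 5q31.2 (chromosome 5, 137688222 to 137688311), 5p12 (chromosome 5, 43105932 to 43106003) and 14q21.3 (chromosome 14, 50328823 to 50329046). All of these peaks were called in both lines and all overlapped a Calu3 CTCF peak.

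Strong peaks of 1 line with no BRD8 peak within 1 kb in the other were also found. In Calu3 they were led by 10p15.1 (chromosome 10, 4891829 to 4892207, rank 29), 5q31.2 (chromosome 5, 139145134 to 139145548, rank 49), 3q26.2 (chromosome 3, 167765065 to 167765313, rank 100), 11p15.1 (chromosome 11, 19092778 to 19093049, rank 112) and 2q13 (chromosome 2, 114361680 to 114362011, rank 117). All 5 overlapped CTCF. In 16HBE14o- they were led by 12q13.3 (chromosome 12, 57400302 to 57400525, rank 16), 3p12.1 (chromosome 3, 87019019 to 87019242, rank 17), 21q22.3 (chromosome 21, 45209242 to 45209465, rank 29), 14q32.33 (chromosome 14, 105512126 to 105512349, rank 32) and 20q13.32 (chromosome 20, 57978848 to 57979071, rank 43). Of these, 3p12.1 alone had no Calu3 CTCF peak. The strongest Calu3 peak absent from both the 16HBE14o- and the CTCF lists, picked after the values were seen, lay in 17p11.2 (chromosome 17, 18529040 to 18529339, rank 163).

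**Figure D1:**
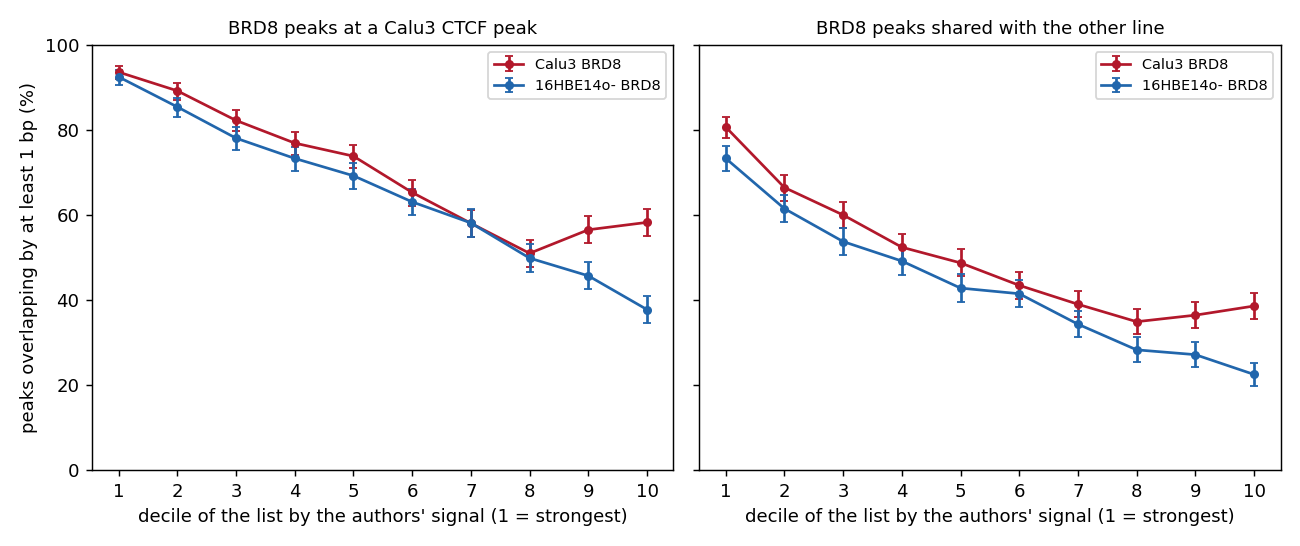
Share of BRD8 peaks (y axis, percent) that overlapped a Calu3 CTCF peak (left) or a BRD8 peak of the other line (right), by decile of the list from the strongest to the weakest authors' signal (x axis). Points are shares and bars 95% exact intervals; CTCF overlap fell from 93.6% to 51.0% over deciles 1 to 8 in Calu3 and then stood at 58.2% in the weakest (39.9% after overlapping peaks were merged, 26.2% with peaks set to 200 bp), while in 16HBE14o- it fell from 92.4% to 37.7%.

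The next comparison asked how far BRD8 and CTCF occupy the same sites. By overlap of at least 1 bp, most BRD8 peaks lay at CTCF peaks: 6883 of 9769 Calu3 BRD8 peaks overlapped a Calu3 CTCF peak, or 70.5% (69.5 to 71.4%), and 41.9% (40.9 to 42.9%) did so by a reciprocal overlap of at least 50%. Of the 16HBE14o- BRD8 peaks, 6204 of 9505 overlapped a Calu3 CTCF peak, or 65.3% (64.3 to 66.2%), and 61.9% (60.9 to 62.8%) did so by the reciprocal rule. That rule is stricter for the wider Calu3 BRD8 peaks. The reverse was less frequent, with BRD8 called at 36.1% of CTCF peaks in Calu3 (35.3 to 36.8%) and, in 16HBE14o-, at 38.0% (37.3 to 38.8%). Random placement of the CTCF peaks met 0.499% of Calu3 BRD8 peaks and 0.317% of 16HBE14o- BRD8 peaks on average. The overlap reached 93.6% in the strongest decile of Calu3 BRD8 peaks and 92.4% in that of 16HBE14o-. A BRD8 peak with CTCF outranked one without with probability 0.686 in Calu3 and 0.715 in 16HBE14o- (permutation p = 1e-05 for each, the smallest possible). The Calu3 share exceeded the 16HBE14o- share by 5.19 percentage points (Fisher's exact test p = 1.3e-14), but with summits within 100 bp the order turned, at 54.8% in Calu3 and 64.3% in 16HBE14o-, and with 1 summit per merged region the shares were 63.7% and 64.2% (Fisher's exact test p = 0.45). CTCF was mapped in Calu3 only, and a site without a listed CTCF peak is not shown to lack CTCF.

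The summits of overlapping peaks lay close together. In Calu3 the median distance between BRD8 and CTCF summits was 37 bp (quartiles 16 and 87 bp), and 60.5% lay within 50 bp (59.3 to 61.7%). For 16HBE14o- BRD8 the median distance to Calu3 CTCF was 19 bp (quartiles 8 and 34 bp), with 89.3% within 50 bp (88.5 to 90.1%). These distances do not show that BRD8 lay closer to CTCF in 16HBE14o-. The usual BRD8 width was 476 bp in Calu3 and 224 bp in 16HBE14o-, and wider peaks can overlap with summits further apart. In Calu3, 1585 BRD8 peaks (16.2%) were called at least 199 bp from a stronger summit they adjoined, against 1 in 16HBE14o-. After overlapping peaks were merged, the Calu3 median was 31 bp. BRD8 summits without an overlapping CTCF peak were a median of 24.7 kb from the nearest CTCF summit in Calu3 and 47.6 kb in 16HBE14o-.

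**Figure D2:**
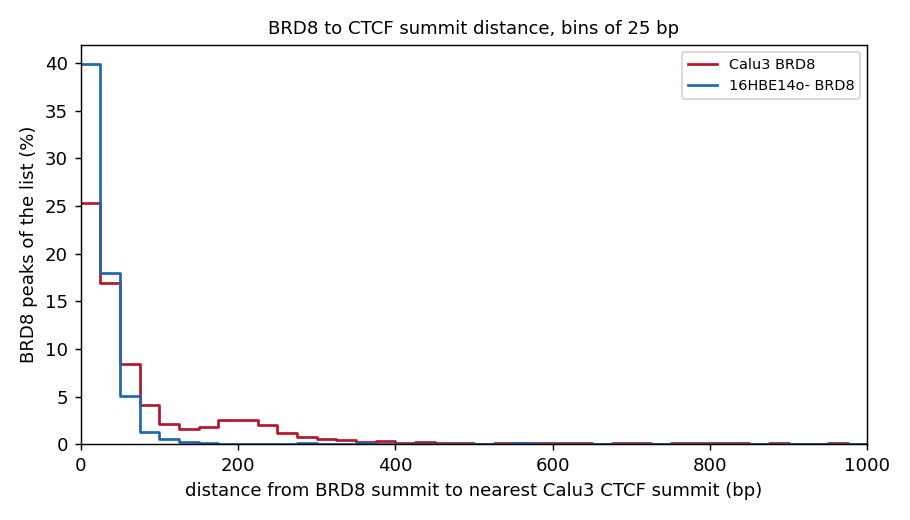
Distance from each BRD8 summit to the nearest Calu3 CTCF summit in bp (x axis) against the percent of that BRD8 list (y axis), in bins of 25 bp, with a line per cell line. The first bin held 25.3% of Calu3 and 39.9% of 16HBE14o- BRD8 peaks, and the Calu3 list had a second, smaller rise of 2.54% between 200 and 225 bp, where 16HBE14o- had 0.0736%. Calu3 BRD8 peaks called beside a stronger peak lay a median of 206 bp from its summit. Whether such peaks make up the rise was not tested.

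Several sites ranked near the top for both proteins. The peaks of highest summed rank lay in 20q13.32 (chromosome 20, 56784786 to 56785386), where BRD8 ranked 1 in Calu3 and 2 in 16HBE14o- and CTCF ranked 3, with BRD8 and CTCF summits 30 bp apart. At 17q12 (chromosome 17, 36762544 to 36763028) CTCF had its highest signal of all, 388.2, BRD8 ranked 3 in Calu3 and 40 in 16HBE14o-, and the summits were 25 bp apart. At 19q13.11 (chromosome 19, 34268913 to 34269382) both proteins ranked 9 in Calu3, with summits 4 bp apart. The others were 7p22.3 (chromosome 7, 1032766 to 1033118), with BRD8 ranked 18 and CTCF 6, and 20q11.21 (chromosome 20, 30200644 to 30200994), with BRD8 ranked 25 and CTCF 2. The remaining CTCF peaks of highest signal lay in 12q13.2 (chromosome 12, 56583264 to 56583571, signal 371.6) and 17q21.31 (chromosome 17, 44270746 to 44271065, signal 364.5).

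BRD8 peaks called in both lines were compared with those of 1 line for CTCF overlap. Shared BRD8 sites were mostly at listed Calu3 CTCF peaks, and sites of 1 line were so about as often as not. In Calu3, 4234 of 4890 shared peaks overlapped CTCF (86.6%, 85.6 to 87.5%), against 2649 of 4879 peaks of Calu3 alone (54.3%, 52.9 to 55.7%). The odds ratio was 5.43 (4.92 to 6.0; Fisher's exact test p = 3.7e-279, 3.7e-279 after adjustment over 2 tests). In 16HBE14o-, 3543 of 4127 shared peaks overlapped CTCF (85.8%, 84.7 to 86.9%), against 2661 of 5378 peaks of that line alone (49.5%, 48.1 to 50.8%), an odds ratio of 6.19 (5.59 to 6.86; Fisher's exact test p = 3e-318, adjusted 6.1e-318). The odds ratio in 16HBE14o- was 1.14 times that in Calu3, with a 95% interval of 0.988 to 1.32 that takes the lists as independent. Which line had the higher odds ratio depended on the rule: with summits within 100 bp it was 10.2 in Calu3 and 6.13 in 16HBE14o- (ratio 0.602, 0.520 to 0.697), and after overlapping peaks were merged the ratio was 1.21 (1.04 to 1.40). Put the other way, 61.5% of Calu3 BRD8 peaks with CTCF were shared, against 22.7% of those without. In 16HBE14o- the shares were 57.1% and 17.7%. Sharing and CTCF overlap were both more frequent among strong peaks, and the odds ratios were not adjusted for signal. How far the link between sharing and CTCF is separate from signal was not tested. For the 16HBE14o- list, sharing and CTCF overlap both need a call in Calu3. Regions poorly detected in Calu3 would lose both and could raise that odds ratio. Any CTCF sites of 16HBE14o- alone count as sites without CTCF in its 49.5%.

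The same held from the side of CTCF. Of 16413 CTCF peaks, 3570 (21.8%) had BRD8 in both lines, 2352 (14.3%) in Calu3 alone, 2668 (16.3%) in 16HBE14o- alone and 7823 (47.7%) in neither. A CTCF peak with BRD8 in one line had higher odds of BRD8 in the other, with an odds ratio of 4.45 (4.16 to 4.76). This odds ratio was not adjusted for CTCF signal, and BRD8 was more frequent at stronger CTCF peaks in both lines. CTCF peaks with BRD8 in both lines had the highest median CTCF signal, 80.1, against 35.3 and 42.5 with BRD8 in Calu3 or 16HBE14o- alone and 27.1 with BRD8 in neither. In the strongest decile of CTCF peaks 73.2% carried BRD8 in Calu3 and 84.5% in 16HBE14o-, and in the weakest decile 12.5% and 9.50%.

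**Figure D3:**
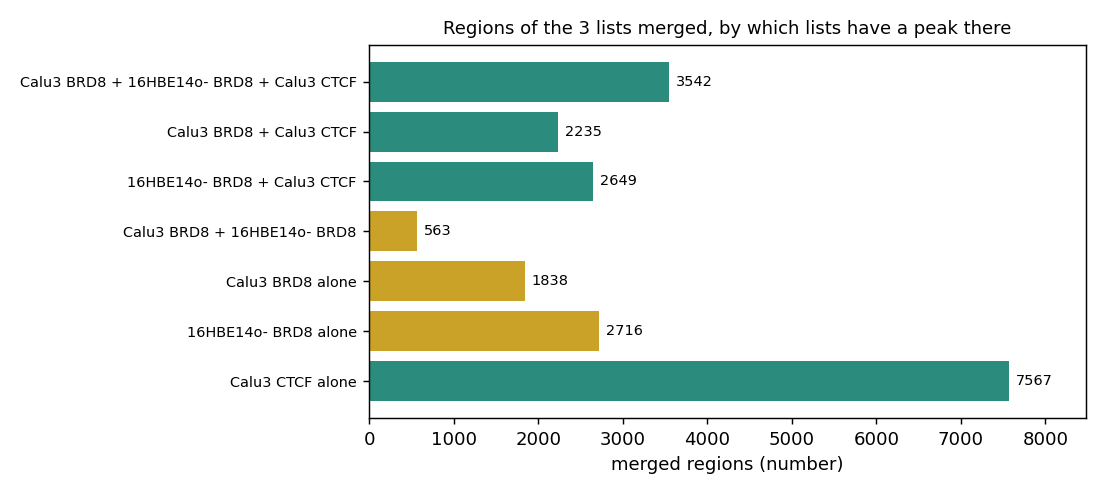
Number of regions (x axis) by which of the 3 lists had a peak there (y axis), after all peaks were merged into 21110 regions; regions with CTCF are green and those without are yellow. All 3 lists met in 3542 regions, whereas 563 regions had BRD8 in both lines without CTCF.

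Merging all peaks gave 21110 regions. CTCF alone accounted for 7567 of them and all 3 lists for 3542. BRD8 with CTCF was found in 2235 regions in Calu3 alone and in 2649 in 16HBE14o- alone. BRD8 without CTCF was found in 1838 regions in Calu3 alone, 2716 in 16HBE14o- alone and 563 in both lines.

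The BRD8 peaks of the 2 lines were distributed differently over chromosome arms, a comparison chosen after the data were examined. Of 41 arms tested, 12 held a larger share of the Calu3 list, 20 a larger share of the 16HBE14o- list, and 9 were not called (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). The short arm of chromosome 11 held 251 Calu3 and 31 16HBE14o- peaks, a ratio of list shares of 7.88 (5.41 to 11.8, Fisher's exact test, adjusted p = 4e-42). On 10p there were 79 and 9 peaks (ratio 8.54, 4.28 to 19.4) and on 3q 820 and 251 (ratio 3.18, 2.76 to 3.68). In the opposite direction, 6q held 112 Calu3 and 355 16HBE14o- peaks, 3.26 times as large a share of the 16HBE14o- list (2.63 to 4.07), 18p held 22 and 91 (4.25 times, 2.65 to 7.12) and 21q 39 and 116 (3.06 times, 2.11 to 4.51). Chromosome 3 as a whole held 11.1% of the Calu3 list and 3.89% of the 16HBE14o- list. Neighbouring peaks are not independent, so these p-values are too small as measures of difference between arms.

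**Figure D4:**
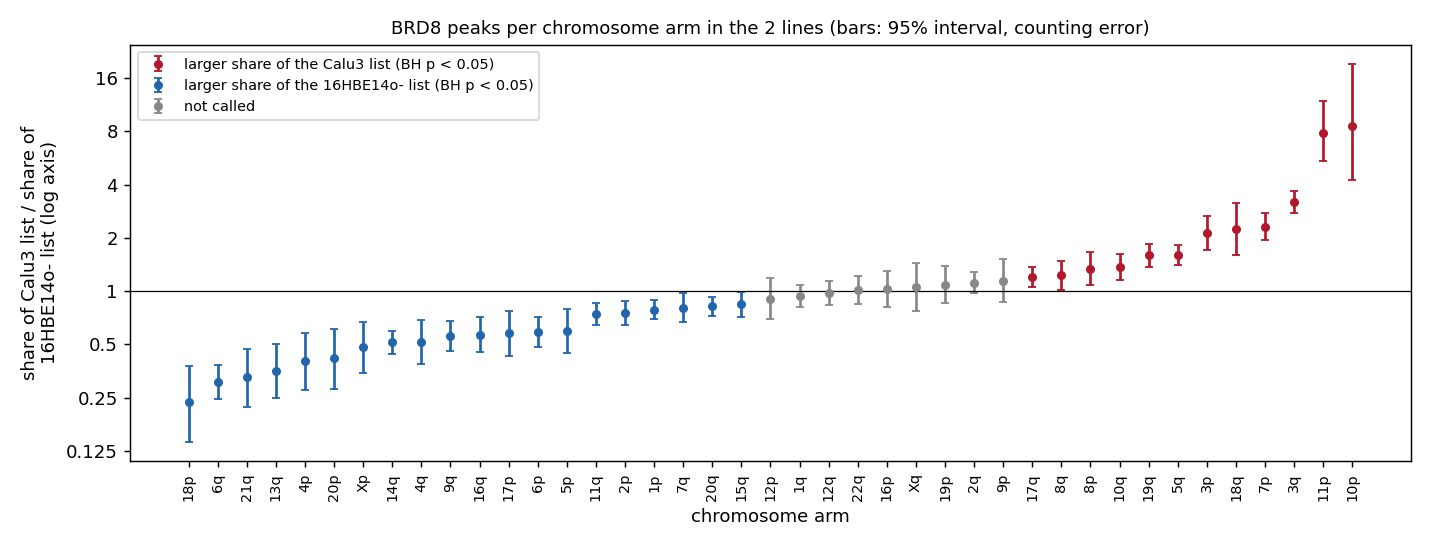
Share of the Calu3 BRD8 list on each chromosome arm divided by the share of the 16HBE14o- BRD8 list (y axis, log scale), for 41 arms in order of the ratio (x axis). Bars are 95% exact intervals for counting error, and colours mark the 12 arms with a larger share in Calu3, the 20 with a larger share in 16HBE14o- and the 9 not called; 10p and 11p stand highest, at 8.54 and 7.88.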

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

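The division by chromosome arm, the test on all CTCF peaks and the test of the difference in CTCF overlap between the lines were chosen after the results were seen. BRD8 peaks were distributed differently between the lines on 6 arms by a factor of at least 3: 10p (8.54), 11p (7.88) and 3q (3.18) in favour of Calu3, and 18p (4.25), 6q (3.26) and 21q (3.06) in favour of 16HBE14o-, with adjusted p from 9.8e-70 for 3q to 5.1e-10 for 21q. The difference was tested on numbers of peaks and was in the same direction for each of these arms in the upper 50% of each list and after overlapping peaks were merged. After merging, 3q and 21q no longer differed by a factor of at least 3, with ratios of list shares, Calu3 over 16HBE14o-, of 2.99 and 0.350.

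The arm differences held alike for BRD8 peaks with and without a listed Calu3 CTCF peak. Over 41 arms, the log2 ratio of peaks of 1 line without a listed CTCF peak followed that of peaks with one (Pearson r = 0.912, Spearman rho = 0.937, r = 0.902 without 10p and 11p, permutation p = 1e-05 for each, the smallest possible, adjusted 2e-05 over 6 relations). The differences were therefore not confined to the listed Calu3 CTCF peaks. CTCF was not mapped in 16HBE14o-, and a site without a listed peak is not shown to lack CTCF. A difference confined to CTCF sites is therefore not excluded. The copy number of whole arms is a candidate explanation: at sites called in both lines, the Calu3 percentile minus the 16HBE14o- percentile rose with the ratio of peaks of 1 line (r = 0.862, rho = 0.819, r = 0.830 without 10p and 11p; permutation p = 1e-05 for each, adjusted 2e-05), although an arm-wide difference in BRD8 occupancy could give the same relation, and copy number itself was not measured. A gain of DNA raises CTCF signal too, but neither test with CTCF decides: the CTCF percentile minus the 16HBE14o- BRD8 percentile followed the ratio (r = 0.786, rho = 0.712, r = 0.676 without 10p and 11p; permutation p = 1e-05 for each), and so did the subtracted 16HBE14o- term by itself (r = 0.614, permutation p = 2e-05). The mean percentile of all CTCF peaks of an arm did not rise with the ratio (r = -0.283, rho = -0.306, permutation p = 0.074 and 0.053, adjusted p of r 0.089; r = -0.282 without 10p and 11p), but the same mean over the Calu3 BRD8 peaks themselves did not follow it either (r = 0.083, permutation p = 0.61), so this measure could not have shown a shift. Copy number and a difference in BRD8 occupancy between the lines therefore cannot be told apart here, for want of a control library or CTCF in 16HBE14o-. Bands of the same arm could also differ in opposite directions. For example, 11q12.1 held 27 Calu3 and 4 16HBE14o- BRD8 peaks, and 11q22.1 held 0 and 26. These bands were picked after the values were seen. A change of the whole arm alone would not give both, and differences of parts of arms were not tested.

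The share of BRD8 peaks at Calu3 CTCF peaks was higher by 5.19 percentage points in Calu3 than in 16HBE14o- (Fisher's exact test p = 1.3e-14), and its direction turned under 4 of the alternatives for overlap and width, in 1 of them by -0.553 points only (Fisher's exact test p = 0.45).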

How the results depend on the processing

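The differences between the lines in CTCF overlap and its odds ratio, with their alternatives, and the alternatives for the share of 16HBE14o- peaks met by Calu3 peaks, for merged regions and for the weakest decile were chosen after the data were seen. Shared BRD8 peaks overlapped CTCF more often than peaks of 1 line under the 8 alternatives run in each line, none of them adjusted for signal or for detection in Calu3. The odds ratios ran from 4.55 to 10.2 in Calu3 and from 4.42 to 9.23 in 16HBE14o-. The value of 9.23 came with the reciprocal overlap of at least 50%, a rule limited by peak width as described below. Under the other alternatives the 16HBE14o- odds ratio was at most 6.25. Shared peaks outranked the others under all alternatives run, with probabilities from 0.636 to 0.691. The ratio of these odds ratios, 16HBE14o- over Calu3, had no stable direction: it was 0.602 with summits within 100 bp, 0.893 with the strongest summits of merged regions, 0.927 with peaks set to 200 bp, 0.972 in the upper 50% of each list and 1.21 after merging, and its interval excluded 1 in the first and last of these. The 12 arm ratios recomputed also kept their direction and passed the test. Shares depended on what counted as overlap. A reciprocal overlap of at least 50% left 4.37% of Calu3 and 4.44% of 16HBE14o- BRD8 peaks shared, and 41.9% and 61.9% at CTCF, a difference of -20.0 points. The usual 16HBE14o- width is 47.1% of the Calu3 width, so this rule excludes most pairs of BRD8 peaks by construction. The usual CTCF width is 290 bp, against 476 bp for Calu3 BRD8 and 224 bp for 16HBE14o- BRD8. The rule is thus also stricter for Calu3 at CTCF. With summits within 100 bp, 39.3% and 40.4% were shared, and 54.8% and 64.3% lay at CTCF, a difference of -9.49 points. With the strongest summit of each merged region instead, 63.7% and 64.2% lay at CTCF, a difference of -0.553 points (Fisher's exact test p = 0.45), so most of that gap came with the secondary summits. With every peak set to 200 bp, 44.8% of Calu3 peaks were shared and 62.8% lay at CTCF, and the difference between the lines was -2.41 points; the cause of the other reversals was not tested. The weakest decile of Calu3 peaks moved from 38.6% shared to 22.3% after merging and 17.7% at 200 bp, without a rise after decile 8 in either. In the upper 50% of each list, which also shortens the list searched, 43.0% of Calu3 peaks were shared, 62.8% of Calu3 and 62.4% of 16HBE14o- peaks lay at CTCF, the difference was 0.319 points (Fisher's exact test p = 0.75), and the median summit distance was 27 bp. With lists of equal length the CTCF list lost its weaker peaks, and 55.1% and 50.9% lay at CTCF. After merging, the median summit distance was 31 bp. On autosomes only, no share left its interval. In all, 42 of 71 values under alternatives to the main comparisons were the same by direction and test, or within the interval. No paired analysis was possible because each list pools both replicates of its experiment. For the same reason no replicate could be left out, and depth is unknown. The alternatives for promoters, gene lists, motif and base composition were not run, since an hg19 annotation and genome were not used here.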

Other observations

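The tests of secondary summits and of a background shared by the Calu3 libraries were written after related values had been seen. All 3 lists favoured the lightly stained, gene-rich part of the genome. In the light Giemsa bands Calu3 BRD8 had 4.88 peaks per Mb and in the darkest bands 0.798, a ratio of 6.11. The ratio was 4.98 for 16HBE14o- BRD8 (4.65 against 0.935 per Mb) and 4.45 for CTCF (8.01 against 1.80 per Mb). In the darkest bands 65.8% of Calu3 BRD8 peaks (60.9 to 70.5%) and 54.3% of 16HBE14o- BRD8 peaks (49.6 to 58.9%) lay at Calu3 CTCF peaks, and in unstained bands 71.0% (69.8 to 72.1%) and 67.8% (66.6 to 69.0%).

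Some bands were nearly exclusive to 1 line. Among 318 bands with at least 20 BRD8 peaks over both lists, 11q22.1 (chromosome 11, 97200001 to 102100000) had 0 Calu3 and 26 16HBE14o- BRD8 peaks, and the adjoining 11q22.2 had 2 and 24. On 6q22.31 the numbers were 1 and 23. In the other direction 12q24.33 (chromosome 12, 129300001 to 133851895) had 22 Calu3 and 0 16HBE14o- BRD8 peaks, 11p15.1 had 31 and 1, 3p22.1 had 26 and 1, and 3q26.2 had 43 and 4. The arm 12q as a whole held 332 BRD8 peaks in each line and was not called. Calu3 CTCF peaks numbered 4 in 11q22.1, 6 in 11q22.2 and 10 in 6q22.31. They numbered 52 in 12q24.33, 49 in 11p15.1, 24 in 3p22.1 and 50 in 3q26.2. Whether the band differences are particular to BRD8 was not tested. These bands were picked as extremes after the values were seen, and a count of 0 in a thresholded list is not evidence that BRD8 is absent.

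BRD8 peaks coincided with Calu3 CTCF peaks in both lines. Crowding of both kinds of peak at a scale of 10 to 100 kb did not account for the overlap. CTCF peaks moved by 10 to 100 kb met at most 1.56% of Calu3 BRD8 peaks in 1000 draws, against 70.5% in place. Crowding within less than 10 kb was not tested. A background shared by the Calu3 libraries, which would favour Calu3 BRD8, stays open as a contribution, because the order of the lines depends on the rule: 70.5% in Calu3 against 65.3% in 16HBE14o- at 1 bp, 54.8% against 64.3% with summits within 100 bp, and 63.7% against 64.2% with 1 summit per merged region. A background common to immunoprecipitations in both lines, such as a preference for open chromatin, was not tested. That BRD8 is present at CTCF sites in both lines is therefore a hypothesis that these lists are consistent with, not one they settle.

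The overlap of Calu3 BRD8 with CTCF fell to 51.0% in decile 8 and then stood at 58.2% in the weakest decile. A candidate explanation is secondary summits called beside a stronger peak, which made up 85.4% of the weakest decile: with 1 peak kept per merged region, the weakest decile overlapped CTCF in 39.9%, below 50.5% in the decile above it. With peaks set to 200 bp the weakest decile stood at 26.2%, below 34.6% in the decile above it. Secondary summits lay at least 199 bp from the stronger summit, so this setting also tends to part them from a CTCF peak there. A contribution of peak width therefore could not be told apart from that of secondary summits. The 1585 secondary peaks lay a median of 206 bp from the stronger summit and never closer than 199 bp, and the 342 in the CTCF list had the same minimum of 199 bp. Such a fixed minimum may come from the spacing that a peak caller allows, which was not tested, and no biological explanation was tested.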
